A study of Homo sapiens with 13 samples.

How the data were processed

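Total RNA of 9 T-ALL samples and 4 normal thymus samples was isolated with a Qiagen kit and depleted of ribosomal RNA before Illumina sequencing, per the labels. Samples were grouped by the tissue that the labels name, and every comparison is of T-ALL against normal thymus. The submitters' processing notes name CASAVA 1.4, STAR, DESeq and the genome build hg19, without versions of STAR and DESeq and without their roles; the gene annotation, the counter, the use of strand and the filter on low genes are not given in the sources used here.

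The deposited table held, per the file headers, 3 mean signal columns per gene: mean read counts divided by library size factors over all 13 libraries, over the control libraries and over the T-ALL libraries. The control column was identified from the submitters' design text, and the overall mean equals the group means weighted by 4 and 9 in every gene. The table also gave the authors' fold change as a linear ratio of T-ALL over thymus and the authors' log2 fold change of the same means. The deposited p-value of each gene and its adjusted p-value are the authors', from DESeq per the file headers, and the adjusted value equals the Benjamini-Hochberg adjustment over the 14018 genes of the table. The table holds no standard errors, and 1 alternative setting derived them from the authors' fold change and p-value. In 2 genes a group mean of 0 makes the deposited fold infinite or 0. In 18 genes the symbol had been turned into a date by a spreadsheet, and these were kept in the counts and left out of lists by name. No gene had an overall mean under 50, so lower genes were not analysed here. That mean weights T-ALL by 9 and thymus by 4, so such a floor more readily leaves out genes high in thymus alone than genes high in T-ALL alone. The lowest nonzero thymus mean, 0.177, was shared by 3 genes and was taken as about 1 read. Depth per library is unknown, so the intervals given for genes with about 1 to 3 reads are exact Poisson intervals at 95%, cover counting error only and leave out the spread between samples.

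Genes were called at an adjusted p of 0.05. For gene lists, log2 of (T-ALL mean + 1) over (thymus mean + 1) was taken for genes with an overall mean of at least 10, and the list median was placed among 10000 random lists of the same size, drawn with replacement from the same of 20 bins of overall mean, with a two-sided p. This p is called a permutation p below; it redraws genes and does not permute samples. It was given a Benjamini-Hochberg adjustment over 31 lists of at least 5 measured genes. The 33 lists (pathways, cell type markers, complexes and noncoding RNA classes) and the rules below were fixed before the data were examined. The mitochondrial genome list matched 0 genes and the T cell receptor segment list matched only TRADD, which is no receptor segment, so neither was tested. Correlation between genes cannot be estimated from group means, so p-values of lists whose members vary together are too small. Of the 31 lists 15 were higher, 9 lower and 7 not past the threshold. Some lists share genes: 8 microRNA host genes are also among the entries named for microRNA genes, and 3 HOXA genes are also among the oncogenes. For 3' UTR sites, 7-base sites of 6 seeds were searched in the longest 3' UTR that the GENCODE annotation lifted to GRCh37 gives for 12864 genes, and compared with 10000 random gene sets matched on mean and 3' UTR length. Of 14018 symbols 12248 matched by name and 1192 through a synonym, and symbols that led to the same gene were left out. Coordinates are GRCh37. Host genes and lengths of short RNA genes came from NCBI RefSeq of GRCh38.p14, used for names, lengths and neighbours only. No measurement of mature microRNAs was used.

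The named genes are MYB and HBP1, up to 4 members per list past the threshold with the largest absolute log2 fold change (or the 2 with the highest mean where none passed), genes from the 10 highest and 10 lowest fold changes among those with a mean of at least 100 and both means above 0, the 5 smallest p-values in each direction, and markers of sample composition. Genes named outside this rule are said to be chosen after their values were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The list test was tested on simulated ratios for the 14018 genes: of lists shifted by 1 on the log2 scale 98.0% were called, of lists shifted by 0.5 52.5%, and of unshifted lists 3.18%. The seed test, with a shift of 0.2 added to miR-29 targets over 12864 genes, gave an excess of 0.190 and called 0 other seeds. That simulation was run once, with a shift larger than any found in the data. Whether the seed test would call shifts of the size found is therefore unknown. The test of a difference of medians gave p under 0.05 in 4.50% of 400 unchanged pairs. Other settings tried were other thresholds, filters, pseudocounts, Bonferroni adjustment, a minimum fold, recentring on the median gene, unmatched random lists, the mean, the signed normal quantile of p, and, for seeds, 8-base sites and no matching on 3' UTR length. Refits of per-sample counts were not possible from group means.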

Results

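The series measured gene expression in total RNA from 9 samples of T-cell acute lymphoblastic leukaemia (T-ALL), a cancer of immature T cells, and from 4 samples of normal thymus, the organ in which T cells mature. The labels describe the leukaemia samples as coming from separate patients and do not say whether the thymus samples came from separate donors. Ribosomal RNA was depleted before sequencing, so transcripts without a poly(A) tail could be read too. The values analysed were the authors' mean normalized read counts per group with the authors' fold changes and p-values. No per-sample values were used, so the depth of each library is unknown and no spread between replicates can be given beside a mean. In the authors' deposited table the group means summed to 27.0 (thymus) and 28.4 (T-ALL) times 1e6 over 14018 genes. Over these genes the lowest overall mean in the authors' deposited table was 54.7 normalized counts and the median was 859.

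The comparison asks which transcripts differ between T-ALL and normal thymus, and the series title places it in the study of a network of tumour suppressor microRNAs. Transcripts of leukaemia-associated transcription factors, progenitor genes, erythroid, granulocyte, monocyte and cytotoxic cell markers, stress-response genes and small nucleolar RNAs were higher in T-ALL. Transcripts of cortical thymocytes, thymic epithelium, connective tissue, antigen presentation and replication-dependent histones were lower. Of 14018 genes in the authors' deposited table, 4178 (29.8%) passed an adjusted p of 0.05, of which 2734 were higher and 1444 lower in T-ALL, so 65.4% of the calls were higher. After recentring on the median gene with recomputed p, an alternative chosen after seeing the data, 2247 were higher and 1741 lower (56.3% higher). Over genes with a mean of at least 200 and 500, alternatives chosen after seeing the data, 69.9% and 71.7% of the calls were higher. The overall mean weights T-ALL more than thymus, so a floor on it more readily leaves out genes high in thymus alone. The floor of the deposited table may thus have raised the share of 65.4%, by an amount that was not tested. At an unadjusted p of 0.05, 5255 genes passed. At least 2-fold differences made up 2155 of the higher and 1205 of the lower calls. The median gene stood at a log2 fold change of 0.13, and the list tests below are relative to genes of like expression, which carry the same shift. With a Bonferroni adjustment 1631 genes passed, and with the adjustment made over genes with a mean of at least 500, an alternative chosen after seeing the data, 2217 passed.

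**Figure D1:**
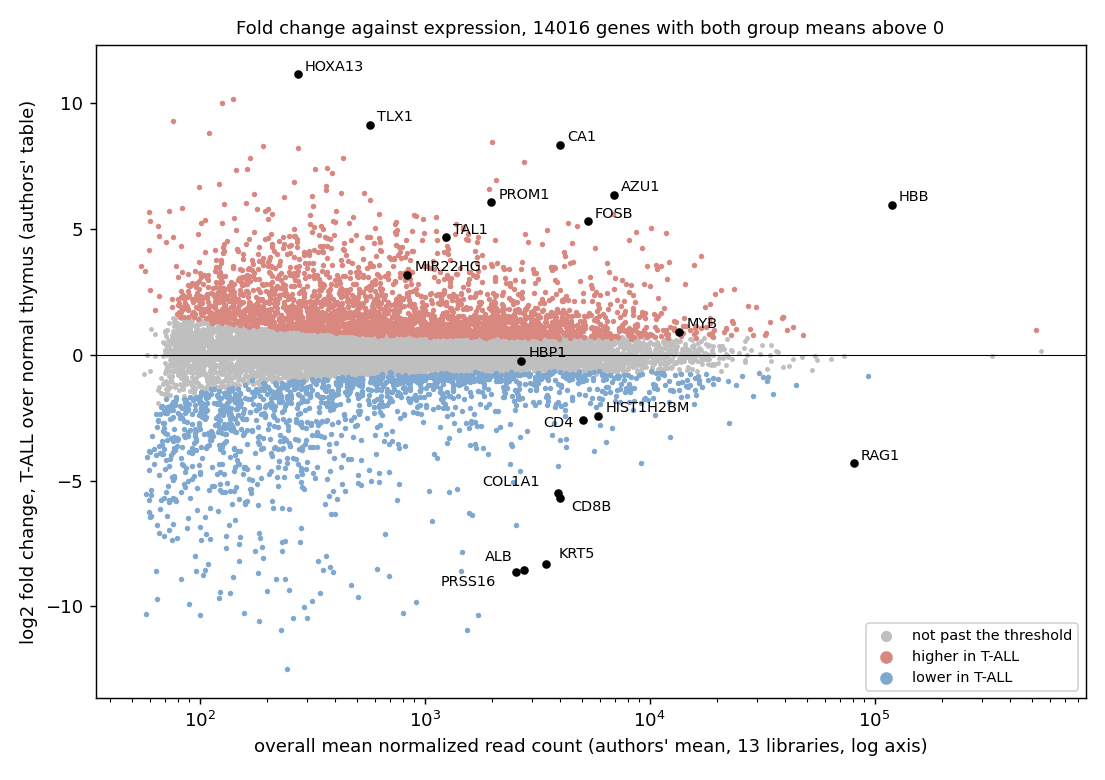
Log2 fold change of T-ALL over normal thymus against the overall mean normalized read count on a log axis, both from the authors' deposited table, for genes with both group means above 0. Red points passed an adjusted p of 0.05 and were higher in T-ALL (2734 genes in all), blue points passed and were lower (1444), grey points did not pass, and black points are named genes: CA1 and TLX1 lie high, KRT5 and ALB low, and HBP1 near 0.

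MYB and HBP1 are the genes known from the study. MYB, a transcription factor of blood progenitors, rose from an authors' mean of 8394 normalized counts in thymus to 15793 in T-ALL, a 1.88-fold difference with an adjusted p of 0.00336 from DESeq in the authors' deposited table. HBP1, a transcriptional repressor of cell cycle genes, had authors' means of 3011 and 2549 in the authors' deposited table, a log2 fold change of -0.24 that did not pass (adjusted p = 0.671). Markers of progenitors and granulocyte precursors rose as given below, so these values do not show which cells account for the rise of MYB. In GRCh37, MYB lies on chromosome 6 at 135502446 to 135540311 on the plus strand, with a longest annotated 3' UTR of 1391 bases. HBP1 lies on chromosome 7 at 106809406 to 106842967 on the plus strand, with a longest 3' UTR of 1091 bases.

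Transcription factor genes that act as oncogenes in T-ALL were higher as a group. Of 14 measured members 12 rose, 1 fell and 1 did not pass, with the same 12 and 1 when adjusted over the list alone. TLX1, a homeobox gene activated by translocation in some T-ALL, stood at an authors' mean of 1.47 in thymus and 821 in T-ALL (log2 fold change 9.12), and TAL1, a basic helix-loop-helix factor, at 70.1 and 1760 (4.65), in the authors' deposited table. LMO2 rose by 3.39 and LYL1 by 2.70 on the log2 scale in the authors' deposited table; both were picked for mention after their values were seen. LMO3 was the exception and fell by 6.20 on the log2 scale in the authors' deposited table. TAL1, LMO2 and LYL1 are also expressed in erythroid and myeloid precursors, whose markers rose as given below, so these values do not show which cells account for their rise. A group mean over patients does not show how many of the 9 T-ALL samples carried a high level of such a gene. The list median of the log2 ratio was 2.18, against -0.29 to 0.65 for the central 95% of matched random lists (adjusted permutation p = 0.000194, the smallest the random lists can give after adjustment). Only 14 of the 21 listed genes were measured. A gene near 0 in thymus, such as TLX1, could enter only through a high T-ALL mean, so the rise may be overstated for the list as a whole.

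Of 9 measured genes of the HOXA cluster, homeobox genes that pattern the body axis and mark blood progenitors, 8 rose and 1 did not pass, over all genes and adjusted over the list alone. HOXA11 rose from an authors' mean of 1.62 to 176 and HOXA6 from 3.87 to 144.5 in the authors' deposited table. HOXA13 rested on about 1 read in thymus against an authors' mean of 394 in T-ALL in the authors' deposited table, a ratio of 2232 with a counting interval of 401 to 88173. HOTTIP, a long noncoding RNA beside HOXA13, was listed at 0 in thymus and at 147.8 in T-ALL in the authors' deposited table. The list median of 4.38 lay outside the random range of -0.93 to 1.13 (adjusted permutation p = 0.000194). Only 9 of the 13 listed genes were measured, and no gene with an overall mean under 50 was available. A gene near 0 in thymus could therefore enter only through a high T-ALL mean. Matching on overall mean does not remove this, so the rise may be overstated for the cluster as a whole. Since progenitor and granulocyte precursor markers rose too, the cells behind the HOXA rise are unknown. Reads of HOXA genes and of antisense transcripts in the cluster may have been shared, since the use of strand in counting is not given in the sources used here.

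Genes of early blood progenitors rose in 16 of 20 members and fell in 0, also when adjusted over the list alone. PROM1, a surface glycoprotein of stem cells, rose from an authors' mean of 42.9 to 2843 and NFE2, an erythroid transcription factor, from 108 to 2417 in the authors' deposited table. SPINK2 rose by 4.35 and HHEX by 3.71 on the log2 scale in the authors' deposited table. The list median was 2.49 (random range -0.20 to 0.51, adjusted permutation p = 0.000194). Erythroid and granulocyte precursor markers rose too, as given below, so these values do not show which cells account for the rise. The list shares 4 genes with the oncogene list, so the groups are not independent. Genes of NOTCH signalling rose in 8 of 17 members and fell in 2 (8 and 3 adjusted over the list alone), with a median of 0.63 (adjusted permutation p = 0.0158). DTX1, HES1 and HES4, transcriptional targets of NOTCH, rose by 2.38, 2.28 and 2.15 on the log2 scale in the authors' deposited table, while PTCRA, the pre-T-cell receptor alpha chain, fell from an authors' mean of 3605 to 451. The NOTCH list was past the threshold with the median and not with the mean of its members (adjusted permutation p = 0.318) or with the mean signed quantile of p (adjusted permutation p = 0.139).

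Genes of T-ALL tumour suppressors did not shift as a group (6 higher and 4 lower of 25, or 6 and 5 adjusted over the list alone; median 0.10, adjusted permutation p = 0.931). WT1, a zinc finger factor, rose by 3.52, CDKN2B by 2.09, CDKN2A by 2.05 and TSPYL2 by 1.81 on the log2 scale in the authors' deposited table. Genes of the BCL2 family, which regulate cell death, rose in 6 of 14 and fell in 2 (7 and 2 adjusted over the list alone; median 0.62, adjusted permutation p = 0.0291). PMAIP1, which promotes cell death, rose from an authors' mean of 345 to 5835, and BCL2L1, which blocks it, fell from 9316 to 3634, in the authors' deposited table. BCL2A1, an inhibitor of cell death, rose by 1.82 and BMF, a promoter of it, fell by 1.67 on the log2 scale in the authors' deposited table. Members of this list thus moved both ways, and the shift was not past the threshold against unmatched lists (adjusted permutation p = 0.0527), with the mean (0.343) or with the signed quantile (0.296).

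Cortical thymocyte genes, which mark the CD4 and CD8 double-positive stage, were lower in T-ALL. Of 20 members 18 fell and 0 rose, also when adjusted over the list alone, and the median log2 ratio was -2.82 (random range -0.17 to 0.43, adjusted permutation p = 0.000194). RAG1, a recombinase of antigen receptor genes, fell from an authors' mean of 236096 to 11795 and RAG2 from 17283 to 1540 in the authors' deposited table. CD8B fell from 12514 to 240.0 in the authors' deposited table. Genes of the T cell receptor complex and its signalling fell in 17 of 24 members and rose in 2 (19 and 2 adjusted over the list alone), with a median of -0.95 (adjusted permutation p = 0.000194). CD8A fell by 3.82, CD4 fell by 2.60 and CD2 fell by 2.06 on the log2 scale in the authors' deposited table. The 2 lists share 3 genes. Genes of mature and regulatory thymocytes moved both ways, 6 higher and 8 lower of 18 (7 and 8 adjusted over the list alone; median -0.10, adjusted permutation p = 0.347). CTLA4 fell by 3.42, IL2RA fell by 2.46 and FOXP3 fell by 2.32, all genes of regulatory T cells, and KLF2, a factor of naive T cells, rose by 2.46 on the log2 scale in the authors' deposited table.

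Markers of other cells of the thymus were mostly lower in T-ALL, beside the fall of the cortical genes. Genes of thymic epithelium, the tissue that supports T cell maturation, fell in 20 of 23 members and rose in 0 (20 and 1 adjusted over the list alone), with a median of -5.39. KRT5, a keratin of basal epithelium, fell from an authors' mean of 11160 to 35.3 and PRSS16, a thymus-specific serine protease, from 8235 to 20.8, in the authors' deposited table. CCL19, a chemokine, fell by 9.83 and KRT15, a basal keratin, fell by 9.79 on the log2 scale in the authors' deposited table. Genes of fibroblasts and extracellular matrix fell in 20 of 21 members, also when adjusted over the list alone, with a median of -3.71; COL1A1 fell from 12122 to 267 and POSTN from 2598 to 2.14 in the authors' deposited table. Endothelial genes fell in 7 and rose in 4 of 13 members (median -0.95, adjusted permutation p = 0.00228; the same numbers adjusted over the list alone), with CDH5, a junction cadherin, at 565 and 2.51 in the authors' deposited table. The endothelial shift turned to 0.38 above random lists when genes with a mean under 200 were left out, and was no longer past the threshold (adjusted permutation p = 0.221), an alternative chosen after seeing the data. The overall mean weights T-ALL by 9 and thymus by 4, so this filter more readily drops genes that fell. It left out CDH5 and EMCN (overall means 176 and 60.7), so the change of sign is partly set by the filter. Dendritic cell genes fell in 6 and rose in 1 of 10 members (median -1.56, adjusted permutation p = 0.00207; the same adjusted over the list alone), and CCL22 fell by 8.08 and CLEC9A fell by 3.67 on the log2 scale in the authors' deposited table. MHC class II genes, which present antigen, fell in 9 of 13 members, or 11 adjusted over the list alone, with a median of -1.47; HLA-DQA1 fell from 3416 to 339.9 and HLA-DPA1 from 9100 to 1402 in the authors' deposited table.

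Markers of erythroid, granulocyte, monocyte and cytotoxic cells were higher in T-ALL, beside the rise of progenitor genes. Erythroid and platelet genes rose in 15 and fell in 2 of 17 members, also when adjusted over the list alone, with a median of 4.22 (random range -0.23 to 0.57). HBB, the beta-globin gene, rose from an authors' mean of 2787 to 170916, CA1, a carbonic anhydrase of red cells, from 18.0 to 5741 and SLC4A1, the red cell anion exchanger, from 419 to 12351, in the authors' deposited table. HBG1 and HBG2, the gamma-globin genes, fell from 2262 to 802 and from 9550 to 1059 in the authors' deposited table. HBA1 and HBA2, the alpha-globin genes, rose 5.59-fold and 3.28-fold there, less than HBB. All of these were picked for mention after their values were seen, and reads may be shared between such near-identical copies. Globin genes thus differed in direction and size, so the ratio of HBB alone does not measure the amount of red cell RNA. Granulocyte precursor genes rose in 13 of 13 members, also when adjusted over the list alone (median 3.52), with AZU1 at 122 and 9977 and ELANE at 195 and 6758 in the authors' deposited table. Macrophage and monocyte genes rose in 12 and fell in 3 of 20 members (12 and 4 adjusted over the list alone; median 1.33), with FCN1, S100A8 and ITGAM higher by 4.40, 3.65 and 3.53 on the log2 scale in the authors' deposited table. The complement genes C1QA, C1QB and C1QC of tissue macrophages had log2 fold changes of -2.58, -2.83 and -3.28 in the authors' deposited table, and with the mean in place of the median the list shift was 0.70 (adjusted permutation p = 0.0212) instead of 1.22. Genes of natural killer and cytotoxic cells rose in 7 of 10 members, also when adjusted over the list alone (median 2.21), with KLRF1 higher by 4.19 on the log2 scale and CTSW by 3.15 in the authors' deposited table. These erythroid, granulocyte, macrophage and cytotoxic lists each reached an adjusted permutation p of 0.000194. B cell genes did not shift as a group (3 higher and 1 lower of 14, also adjusted over the list alone; median 0.52, adjusted permutation p = 0.211), with BLK, a kinase, higher by 3.44, and MS4A1, which encodes CD20, fell by 1.49 on the log2 scale in the authors' deposited table.

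Immediate early and stress-response genes rose in 18 and fell in 2 of 23 members, also when adjusted over the list alone, with a median of 2.13 (random range -0.20 to 0.43, adjusted permutation p = 0.000194). FOSB rose from an authors' mean of 193 to 7574, FOS from 1325 to 17062 and ATF3 from 89.9 to 2163, all transcription factors of early response, in the authors' deposited table. PPP1R15A, a stress-induced phosphatase subunit, rose by 4.24 on the log2 scale in the authors' deposited table. Monocyte and granulocyte precursor markers rose too, and handling of the samples and RNA quality were not analysed here, so the source of the rise is open. Interferon-stimulated genes did not shift as a group (6 higher and 3 lower of 20, also adjusted over the list alone; median 0.16, adjusted permutation p = 0.881), and IFI27 fell by 3.18 and XAF1 rose by 1.52 on the log2 scale in the authors' deposited table. The direction of this list turned with the mean in place of the median.

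Genes of the cell cycle were lower as a group, by less than the histone genes. Of 34 cell cycle genes 11 fell and 0 rose (12 and 0 adjusted over the list alone; median -0.33, random range -0.11 to 0.35, adjusted permutation p = 0.000912). CCNB1, TOP2A, CCNA2 and BIRC5, genes of G2 phase and mitosis, had log2 fold changes of -1.04, -1.02, -0.97 and -0.97 in the authors' deposited table. Replication-dependent histone genes, which are transcribed in S phase and lack a poly(A) tail, fell in 28 of 30 members (29 adjusted over the list alone), with a median of -1.61 (random range -0.17 to 0.36, adjusted permutation p = 0.000194). HIST1H2BM fell by 2.42 and HIST1H3J by 2.09 on the log2 scale in the authors' deposited table; reads may be shared between these similar genes. Cytosolic ribosomal protein genes rose in 4 of 76 members (3 adjusted over the list alone) and did not shift (median -0.07, adjusted permutation p = 0.119), with RPS26 at 115 and 416 and RPS27 at 593 and 1671 in the authors' deposited table. Ribosome biogenesis genes rose in 4 of 27 members (3 adjusted over the list alone; median 0.38, adjusted permutation p = 0.104), with NOP58, a core protein of box C/D small nucleolar ribonucleoproteins, higher by 1.15 on the log2 scale in the authors' deposited table.

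Small nucleolar RNA (snoRNA) genes, which guide modification of ribosomal RNA, rose in 103 members, fell in 0 and did not pass in 38 (119 rose adjusted over the list alone), with a median log2 ratio of 1.31 (random range -0.03 to 0.34, adjusted permutation p = 0.000194). In tests chosen after the values were seen, the ratio fell with gene length within box C/D snoRNA genes (Spearman's rho -0.47, permutation p = 9e-05) and not within box H/ACA genes (rho 0.010, permutation p = 0.931). A difference in the recovery of short RNA is therefore not excluded in either class. These tests treated snoRNA genes of a shared host gene as independent, so the p within box C/D genes may be too small. SNORA81 rose from an authors' mean of 875 to 6707 and SNORD12C from 33.2 to 288 in the authors' deposited table. Long intergenic RNA genes rose in 12 of 29 members (12 adjusted over the list alone; median 0.82, adjusted permutation p = 0.00945), with LINC00461 at 1.42 and 233 in the authors' deposited table. With genes under a mean of 200 left out, the shift of this list was -0.0039 relative to random lists (adjusted permutation p = 0.988). Entries named for microRNA genes rose in 17 and fell in 2 of 28 members (19 and 2 adjusted over the list alone), with a median of 1.52 (adjusted permutation p = 0.000194). MIR21 rose from 8.48 to 248 and MIR650 from 28.2 to 301 in the authors' deposited table. Reads of such short entries may come from longer overlapping transcripts, so these values do not show a rise of the microRNAs. MIR205HG, a host transcript, rested on about 2 reads in T-ALL and stood at 326 in thymus in the authors' deposited table, a ratio of 1300 with a counting interval of 360 to 10739.

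The microRNAs themselves were approached through their genes, their known targets and the sequence of 3' UTRs. Of 32 listed microRNA genes and host transcripts only 9 were measured. Of these 9, 5 rose and 1 fell, also when adjusted over the list alone (median 1.29, adjusted permutation p = 0.0243; 0.379 with the mean and 0.118 with the signed quantile). No gene or host transcript of the miR-29, miR-31, miR-150 or miR-200 families was among the 9, so this list says nothing about them. MIR22HG rose from an authors' mean of 127 to 1149 and MIRLET7BHG from 73.9 to 479, while MIR100HG fell from 404 to 11.7, in the authors' deposited table. MIR155HG, the host of miR-155, stood at 234 and 253 and did not pass in the authors' deposited table, and was picked for mention after its values were seen. Genes that process microRNAs or act with them did not shift (2 higher of 20, or 1 adjusted over the list alone; median 0.23, adjusted permutation p = 0.468), with DDX5, an RNA helicase, higher by 0.97 and EIF2C4, an Argonaute gene, by 0.78 on the log2 scale in the authors' deposited table. Published targets of the miR-29, miR-31, miR-150, miR-155 and miR-200 families rose in 9 and fell in 1 of 20 members (10 and 2 adjusted over the list alone; median 0.55, adjusted permutation p = 0.0142; 0.326 with the mean and 0.140 with the signed quantile). CEBPB, SPI1 and ZEB2, transcription factors, rose by 2.42, 1.66 and 1.49, and FOXP3 fell by 2.32, on the log2 scale in the authors' deposited table. SPI1, CEBPB and ZEB2 are also expressed in myeloid cells, whose markers rose as given above, and the list holds MYB and HBP1.

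**Figure D2:**
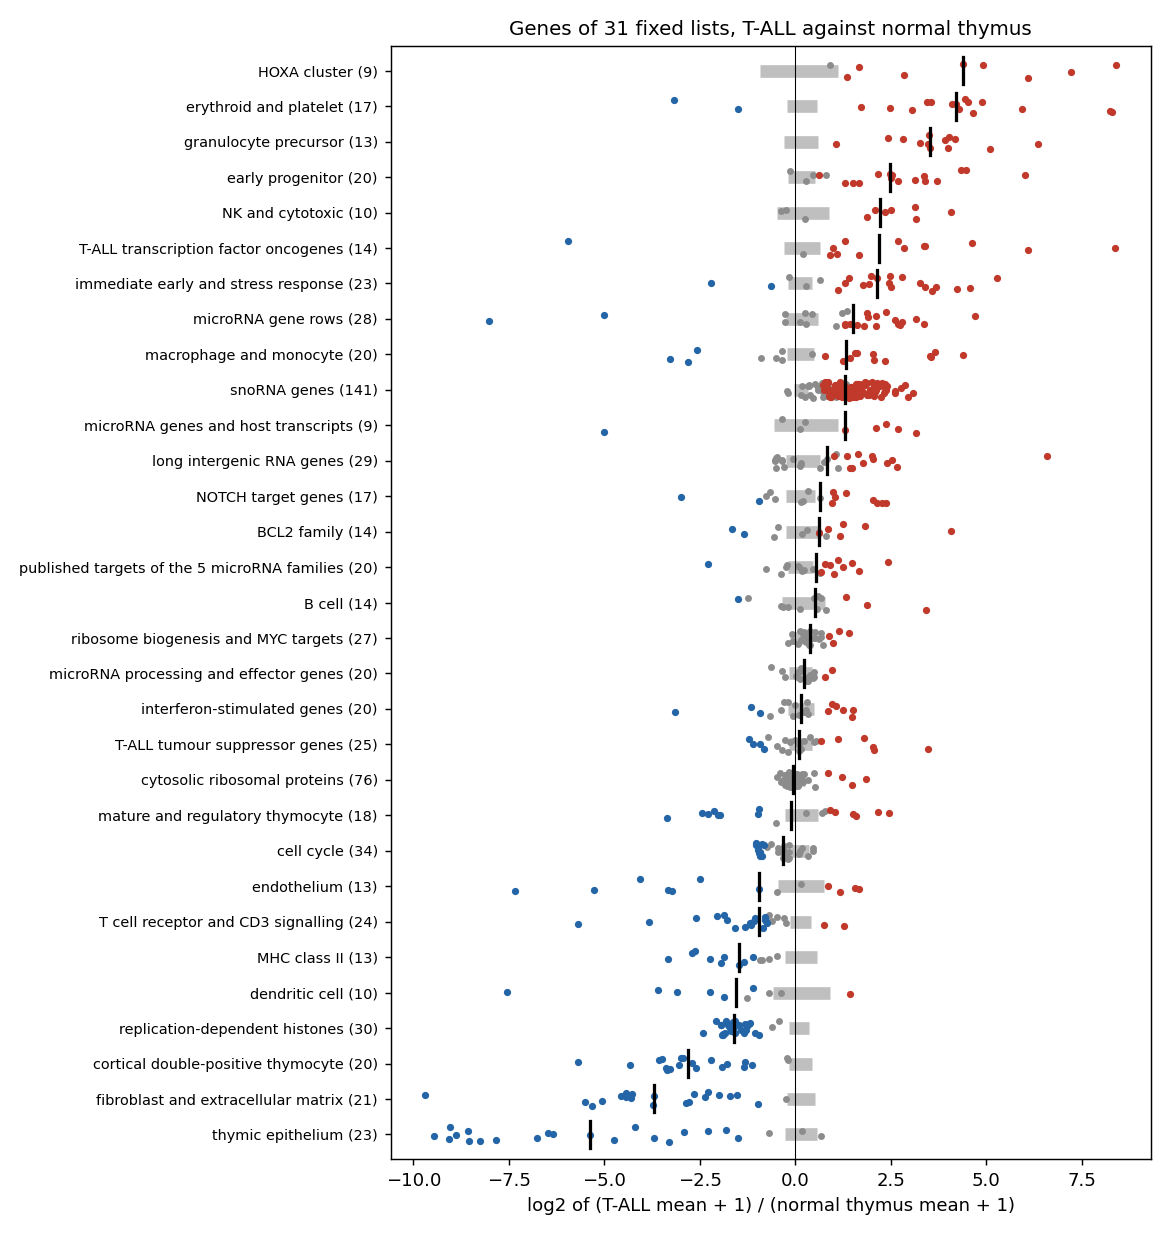
Log2 ratio of T-ALL over normal thymus group means with 1 count added, for the measured genes of each fixed list (number of genes in brackets); red and blue points passed the authors' adjusted p of 0.05 higher or lower, grey points did not, the black tick is the list median and the grey bar the central 95% of matched random lists. Medians run from -5.39 for thymic epithelium to 4.38 for the HOXA cluster.

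Sites for the 6 seeds in the longest annotated 3' UTR did not set genes apart at an adjusted p of 0.05. The miR-155 site, AGCATTA, was carried by 1660 of 12864 genes with a 3' UTR, whose median log2 ratio was 0.04 lower relative to genes matched on expression and 3' UTR length (difference -0.043, adjusted permutation p = 0.0663). The shifts of the site CAGTATT of miR-200b, miR-200c and miR-429 (-0.041, adjusted permutation p = 0.0546) and of the site CAGTGTT of miR-200a and miR-141 (-0.033, adjusted permutation p = 0.0674) were of like size, and all 3 lay past the lower end of the random range before adjustment (permutation p = 0.022, 0.0091 and 0.034). The sites of miR-29 (TGGTGCT), miR-31 (TCTTGCC) and miR-150 (TTGGGAG) gave 0.0042, 0.015 and 0.022, with adjusted permutation p of 0.755, 0.490 and 0.198. Among all words of the same GC count the 6 sites ranked between the 28.3 and 57.6 percentile. AGCATTA, CAGTATT and CAGTGTT stood at 35.0, 55.2 and 28.8, where a low percentile means a lower ratio. Differences like theirs were thus common among words of the same GC count. The permutation p-values of these 3 sites are therefore not particular to microRNA sites. The 3' UTR of MYB held 3 miR-150, 2 miR-155 and 2 CAGTATT sites, and that of HBP1 2 miR-29 sites and 1 miR-155 site. Without matching on 3' UTR length the shifts of miR-155, CAGTATT and CAGTGTT sites passed the threshold (-0.067, -0.067 and -0.059; adjusted permutation p = 0.0040, 0.0006 and 0.0015). Over genes with a mean of at least 200, an alternative chosen after seeing the data, they shrank to -0.014, -0.017 and -0.019 (adjusted permutation p = 0.477, 0.367 and 0.362), and with 8-base sites they were -0.019, -0.066 and -0.026, not past the threshold. The result for these 3 sites thus depends on the matching and on the genes included.

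**Figure D3:**
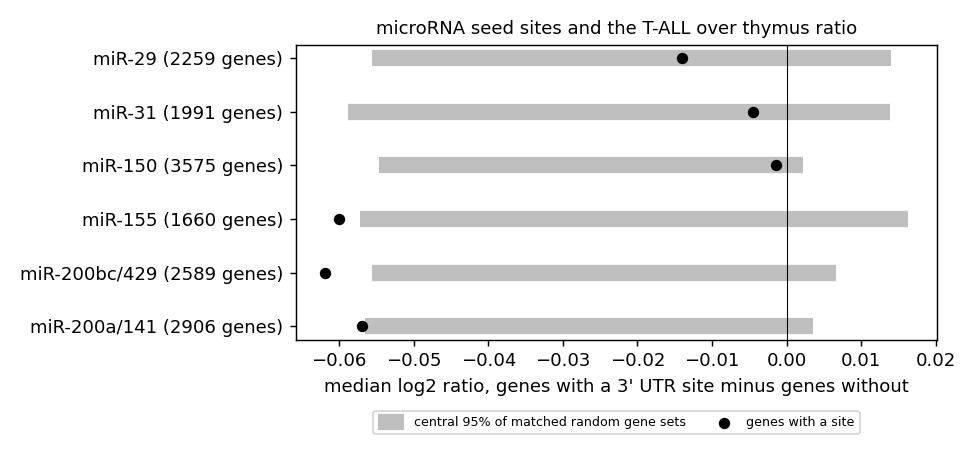
Difference in median log2 ratio between genes with and without a 3' UTR site for each microRNA seed (black points; number of genes with a site in brackets) and the central 95% of 10000 random gene sets matched on expression and 3' UTR length (grey bars). The points lie between -0.062 and -0.0014; those of miR-155 and the 2 miR-200 seeds lie just past the lower end of their bars and the other 3 within them.

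Over all genes, the largest fold changes lay mostly in genes near 0 in one group. HOXC13, PRDM12 and IRX4, transcription factor genes, rested on about 1, 1 and 2 reads in thymus, with ratios of 1145 (205 to 45216), 1007 (181 to 39776) and 450 (125 to 3720) in the authors' deposited table. KIR3DL2, a natural killer cell receptor, BIRC7, an inhibitor of apoptosis, and LOC100506421 had log2 fold changes of 8.19, 7.82 and 8.28 in the authors' deposited table. In the other direction FRMD1 rested on about 1 read in T-ALL, with a ratio of 5652 (1014 to 223234), and KRT14 and AFP on about 3 reads, with ratios of 1966 (673 to 9536) and 1527 (522 to 7404), from the authors' deposited table. CALML3, a calmodulin-like gene, C10orf27, IRS4 and PAX1, a thymic transcription factor, had log2 fold changes of -10.92, -10.34, -10.47 and -10.44 in the authors' deposited table. By p-value, CA1, HBD, L1TD1, DPEP1 and HBB led the higher genes, with adjusted p between 3.00e-87 and 5.57e-63 in the authors' deposited table, and CALML3, C10orf27, ALB, KRT5 and PRSS16 led the lower genes, between 3.04e-61 and 4.23e-53.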

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

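No test below used per-sample values, so leaving out samples, refits with other tools or normalizations, and other splits of the samples were not run. No paired analysis was possible because the table gives group means only, although samples of both groups share the numbers 2, 3 and 4. Filters at means of 10 and 50 removed 0 genes and test nothing. Alternatives with means of 200 or 500, the recentring with an implied standard error and the run without markers of other cell types were chosen after seeing the data. The number of genes past the threshold, 4178, fell to 1631 (1040 higher, 591 lower) with Bonferroni adjustment, a stricter rule by construction, and to 2217 (1589 and 628) over genes with a mean of at least 500, where fewer genes were tested. It ranged from 3108 to 4883 at thresholds of 0.01 and 0.1, was 3195 over means of at least 200, 3360 with a minimum 2-fold difference, 3988 after recentring with recomputed p and 4064 without markers of other cell types. Recentring that only drops calls whose sign changes kept 4178 calls and also tests nothing, since the called genes differed by more than the shift. Recentring with recomputed p moved the share of higher calls from 65.4% to 56.3%. Over means of at least 200 and 500 this share was 69.9% and 71.7%. Across the alternatives other than those filters, 169 list results kept their direction and side of the threshold, 9 lost the threshold with the same sign and 6 changed sign, of which the endothelial and long intergenic RNA lists lost the threshold too; over means of at least 200 the HOXA and dendritic cell lists kept 3 and 4 genes and were not tested. Over means of at least 200, mature thymocyte (0.39), endothelial (0.38) and long intergenic RNA (-0.0039) shifts changed sign. The overall mean weights T-ALL by 9 and thymus by 4, so this filter more readily drops genes that fell. Among them were CTLA4, IL2RA and FOXP3 (overall means 96.4, 107 and 105), so the mature thymocyte and endothelial sign changes are partly set by the filter. With the mean, tumour suppressor (0.11) and interferon (-0.12) shifts changed sign, and with the signed quantile interferon again (-0.054). With 8-base sites the miR-29, miR-31 and miR-150 shifts turned to -0.071, -0.028 and -0.021, and without matching on 3' UTR length to -0.015, -0.0076 and -0.0037, none past the threshold. Without that matching the sites of miR-155 (-0.067), of miR-200b, miR-200c and miR-429 (-0.067) and of miR-200a and miR-141 (-0.059) passed it, while over means of at least 200 they shrank to -0.014, -0.017 and -0.019. The cause was not tested.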

Other observations

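Some genes typical of liver and striated muscle were lower in T-ALL. Lists of such genes were made after low members had been seen, so they describe these genes and test nothing. Of 14 measured genes of plasma proteins secreted by liver 11 fell and 1 rose, with a median log2 ratio of -3.40. ALB, serum albumin, stood at an authors' mean of 8963 in thymus and 23.6 in T-ALL, APOB, the main protein of low-density lipoprotein, at 1225 and 3.55, and AHSG at 420 and 2.87, in the authors' deposited table. HP, haptoglobin, went the other way, with a log2 fold change of 3.04 in the authors' deposited table. Of 22 genes of striated muscle contraction 18 fell and 0 rose, with a median of -4.55. MYH8, a myosin heavy chain, stood at 1644 and 2.07, ACTC1, an actin, at 941 and 0.91 and CKM, muscle creatine kinase, at 667 and 22.8, while TTN, titin, stood at 30597 and 31243, in the authors' deposited table.

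Gene families read from the opening letters of the symbol, 83 with at least 15 members, were compared after the values were seen. Keratin genes fell in 10 and rose in 2 of 15 (median -3.53, adjusted permutation p = 0.0021), and collagen genes fell in 21 and rose in 5 of 37 (median -2.10, adjusted permutation p = 0.0021). The rising keratins were KRT72 and KRT73, with log2 fold changes of 5.27 and 4.62 in the authors' deposited table. C-type lectin genes rose in 8 and fell in 4 of 15 (median 1.49, adjusted permutation p = 0.0083). Genes with symbols in ATP, many of them subunits of the mitochondrial ATP synthase and of proton pumps, were shifted by -0.41 relative to random lists (adjusted permutation p = 0.0021), with 10 higher and 8 lower of 70. Symbols in HIST fell in 52 of 60 (median -1.42, adjusted permutation p = 0.0021), in CD rose in 21 and fell in 27 of 80 (shift -0.29, adjusted permutation p = 0.026) and in COX rose in 1 and fell in 2 of 22 (shift -0.50, adjusted permutation p = 0.0498). Both scans were repeated with 20 other random draws: COX was past the threshold in 3, CD in 19 and the other families named here in 20. By chromosome, genes of chromosome 5 lay lower than random lists (shift -0.27, adjusted permutation p = 0.0022), and genes of chromosomes 17, 19 and 22 higher by 0.11, 0.099 and 0.13 (adjusted permutation p = 0.0022, 0.0073 and 0.039). Chromosome 2 (shift -0.074, adjusted permutation p = 0.052) was past the threshold in 18 of those 20 draws, and chromosomes 5, 17, 19 and 22 in 20.

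Tests in this part were chosen after the result was seen, except the test of snoRNA host genes, which was set before its result was seen. The first pattern is the fall of cortical thymocyte genes. A smaller share of T-lineage RNA would lower T cell receptor and CD3 genes alike, provided that the other cells lack their transcripts. The 20 cortical genes lay 2.01 lower on the log2 scale than the 21 receptor and CD3 genes outside that list (difference -2.01, bootstrap 95% interval -2.51 to -0.92, permutation p = 9e-05). Dilution by cells without receptor and CD3 transcripts therefore cannot account for the whole pattern. Cytotoxic cell markers rose in T-ALL, and expression of some of the 21 genes in such cells was not examined. Dilution by such cells is therefore not excluded. A difference in the stage of the T-lineage cells is a candidate explanation that was not tested, and the loss of thymic stroma remains open as a contribution to the stromal lists.

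The second pattern is the rise of snoRNA genes. Higher transcription of host genes was examined in 116 snoRNA genes with 1 measured host, taken by position without regard to strand. Over 66 hosts the snoRNA ratio exceeded the host ratio by a median of 0.84 (0.56 to 1.09, sign-flip permutation p = 1e-05). The rise in host RNA level was thus smaller than that of the snoRNA genes. Host RNA level also depends on the stability of the host RNA, so the share of the rise due to host transcription is not settled. Other short noncoding RNA genes were drawn from small Cajal body RNA, small nuclear RNA and further classes. Small Cajal body RNA genes are close in kind to snoRNA genes, so this comparison set is not fully separate from them. Against 23 such genes the snoRNA median was 0.86 higher (permutation p = 4e-05). The rule written for this test counted that difference against better recovery of short RNA. That rule was wrong, because the 23 genes were longer (median 187 against 130 bases): within 100 to 200 bases the difference was 0.48 (permutation p = 0.00865). A test of length within snoRNA genes was therefore added after this result was seen. Box C/D genes (median 77 bases) had a median ratio of 1.68 and box H/ACA genes (134 bases) 1.15, so length and class go together. Within box C/D genes the ratio fell with length (Spearman's rho -0.47, bootstrap 95% interval -0.67 to -0.24, permutation p = 9e-05). Better recovery of the shortest RNA in the T-ALL libraries thus remains a candidate explanation for these genes. Several box C/D genes share a host, such as SNHG1 or GAS5, and were treated as independent. This p may therefore be too small and the interval too narrow, and a contrast between hosts was not separated from length. Of 18 microRNA hairpin genes 12 rose, but their reads may come from longer overlapping transcripts, so they do not decide on recovery. Within box H/ACA genes, which span 121 to 250 bases, no trend was seen (rho 0.010, interval -0.23 to 0.26, permutation p = 0.931). For box H/ACA genes recovery and a biological difference cannot be told apart, since the range of lengths is narrow. The labels give the same isolation kit and ribosomal RNA depletion for both groups and no batch. A difference between T-ALL and thymus cells in snoRNA levels stays open and untested.

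The third pattern is the fall of replication-dependent histone genes. The test of fewer dividing cells assumed that cell cycle genes would then fall as much as histone genes. Histone genes lay below them (difference -1.28, 95% interval -1.44 to -0.85, permutation p = 1e-05). Of 16 G1/S and replication genes, a division of the list made after the values were seen, 0 fell and 0 rose, against 11 of 16 G2 and mitosis genes that fell. Histone genes are transcribed in S phase and need not change by the same amount as this mixed list. The difference therefore does not exclude fewer dividing cells. Loss of short RNA would lower snoRNA genes too, but their median was 1.31. Loss of RNA without a poly(A) tail would lower the 11 other short noncoding RNA genes of at least 200 bases, of which 2 rose and 0 fell, but histone genes lay below them (difference -1.76, 95% interval -2.27 to -1.50, permutation p = 1e-05). Such a loss masked by better recovery of short RNA is not excluded. The cause of the fall is thus not settled, and fewer dividing cells stays open. A difference in histone transcription or in the processing of histone RNA is a further hypothesis that these data do not test.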
